A study of Drosophila melanogaster with 2 samples.

How the data were processed

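Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster prepupae of mixed sex, per the labels. The animals carried CG6276 fused at its C-terminus to enhanced green fluorescent protein (eGFP), and chromatin bound by the fusion was precipitated with an antibody against GFP. The labels name 2 biological replicates of this single group, numbered 2 and 4. Chromatin was sonicated to a size range of 200 to 800 bp, per the labels.

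Only peak lists were analysed here. Per the deposited documentation, each replicate list was made from the alignment of that library together with 1 further file that is not described there, the pooled list from both alignments and that file, and the thresholded list from the 2 replicate lists and the pooled list by the irreproducible discovery rate (IDR) procedure. The aligner, the peak caller, the IDR threshold and the sequencing depth are not given in the sources used here, so depth is unknown and intervals below cover the counting of peaks or genes only. The labels name a possible control experiment, and no control library was analysed here.

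The deposited lists have no header line. Their signal value per peak is a score set by the authors' peak caller, and it served here only to rank, split or describe peaks within 1 list. The authors also deposited a −log10 q-value per peak, which was capped: 53.6% of the IDR-thresholded peaks had the highest value, 3.89. It was not used to rank peaks. The authors labelled the pooled list as peaks and background for input to the IDR procedure. Its lowest −log10 q-value was 0.525, and those of replicates 2 and 4 were 0.486 and 0.481. Each list was deposited on genome builds dm6 and dm3. All positions below are dm6 and 1-based, and no coordinate was converted between builds. The largest peak end on each of chromosomes 2L, 2R, 3L, 3R, 4 and X lay within the length of the Release 6 reference sequence. Gene models came from Ensembl release 115 (BDGP6.54) for those chromosomes.

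Peaks of different lists were matched where they shared at least 50% of both lengths, with the nearest summit taken where several did. Most replicate peaks were 436 bp wide (89.0% in replicate 2 and 91.1% in replicate 4), so much narrower or wider peaks could fail this rule. A failed match therefore does not show that a replicate had no peak there. The strongest N peaks of each replicate were compared with N set to the number of IDR-thresholded peaks. Shares were given 95% Wilson intervals. The comparison set for the IDR-thresholded peaks was the 20862 peaks of the pooled list that did not overlap any of them. This set can include background, so it is not a set of bound sites. Expected values came from 100 seeded random placements of the same intervals on the same chromosomes. A promoter peak had its summit within 500 bp of an annotated transcript start, and the other classes were 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic, in that order of precedence.

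Gene groups were 30 lists fixed before the data were examined, 27 of protein-coding genes and 3 of non-coding genes. Of their symbols 6 did not match the annotation: nrd, Z4, calypso, Tor, Lobe and Dl. The Notch list therefore lacked Dl, and the insulin and TOR list lacked Tor and Lobe. Members with a promoter peak were compared with all other genes of the same background by two-sided Fisher exact tests. Sequence windows reached 100 bp to each side of a summit, and each was paired with a window of the same 201 bp length centred 500 bp away on a seeded random side. Matches to 27 published consensus sequences and to all 8192 7-mers (each joined with its reverse complement) were compared between paired windows by exact two-sided sign tests. As an alternative chosen after the data were seen, summit windows were compared with 21978 random windows of the same GC count, and summits outside chromosome 2 with 14349 such windows for an extended CAGTG core whose surroundings were learnt on chromosome 2. Promoter sequence from 100 bp upstream to 50 bp downstream of the most upstream start of each protein-coding gene was compared between bound and unbound promoters by two-sided Fisher exact tests. A logistic model added log2 number of distinct starts and log2 gene length as covariates, with Wald intervals and p-values, as an alternative chosen after the data were seen. Medians of ratios were given bootstrap intervals from 1000 draws. Adjusted p-values were Benjamini-Hochberg values within each family, with a threshold of 0.05. Peaks and genes were the units of these tests and are not independent replicates, so the p-values describe this pair of libraries.

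The named genes followed a rule fixed before the data were examined: CG6276, the genes nearest to the 15 strongest IDR-thresholded peaks matched in both replicate lists, the 3 members with the strongest promoter peak of each list past the threshold (with up to 2 unbound members, in alphabetical order, of lists below background), up to 2 members of every other list, and the 5 leading 7-mers of each direction. Alternatives covered the overlap rule, N, the stronger part of the peak list, each replicate alone, the promoter window, the background genes, the sequence window and the control windows.

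Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. The procedures were tested on simulated data. For the 7-mers, a sequence planted in 5% of windows was called among 8192 tested, together with 2 overlapping 7-mers and no other. Both simulated windows lay 500 bp from a summit, so the simulation did not include the difference in GC content between real summit and control windows. For the gene groups, over 13945 genes, the list of cytosolic ribosomal protein genes, planted with 3 times the share of bound genes, was called in 98 of 100 rounds, and 0.231% of unplanted lists were called. All other genes were drawn independently at a common rate, whatever their number of starts or length. The shares of false calls in these simulations therefore need not hold for the data. For the replicate overlap, 62.2% of peaks were matched where 60% had been planted and the rest placed at random.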

Results

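Binding of the protein encoded by CG6276 was mapped in prepupae, the stage at which larval tissues begin to be replaced by adult ones. The data were 2 biological replicates of a single group, numbered 2 and 4, each with a list of 30000 peaks. A pooled list, labelled by the authors as peaks and background, also held 30000 entries. Of these, 7326 passed the authors' IDR threshold (6760 regions once overlapping peaks were joined). The median IDR-thresholded peak was 450 bp wide with a signal value of 251.5. Sequencing depth is unknown.

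The strongest peaks ranked high in both replicate lists. The strongest of all lay in an intron of dnr1 on chromosome 2R from 22569679 to 22570548, with CG11362 the gene of the nearest start, and it ranked 1 in replicate 2 and 1 in replicate 4. The peak 30 bp upstream of Ugalt, which encodes a UDP-galactose transporter, ranked 2 in both (chromosome X, 2703670 to 2704087), and the peak at PNPase, a polynucleotide phosphorylase gene, ranked 4 and 3 (chromosome 3R, 31404465 to 31404846, 80 bp downstream of a start). Of the strongest 7326 peaks of replicate 4, 59.9% (95% interval 58.7% to 61.0%) were found among those of replicate 2, and in the opposite direction 4397 of 7326 were. Random placement gave 1.52% on average and at most 1.91%, and the weakest 7326 peaks of the replicates shared 11.5%. In that last comparison a match to a stronger peak of the other replicate did not count. Across the 5516 IDR-thresholded peaks matched in both replicate lists, signal values had a Spearman rho of 0.686 and a Pearson r of 0.766 on the log2 scale. These are correlations across peaks, which are not independent replicates. The peaks were also selected by the IDR procedure from these same replicate lists, so the correlations are not independent evidence of agreement. The shared percentage depends on the overlap rule, from 42.0% with at least 80% of both lengths to 73.7% with at least 1 bp.

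**Figure D1:**
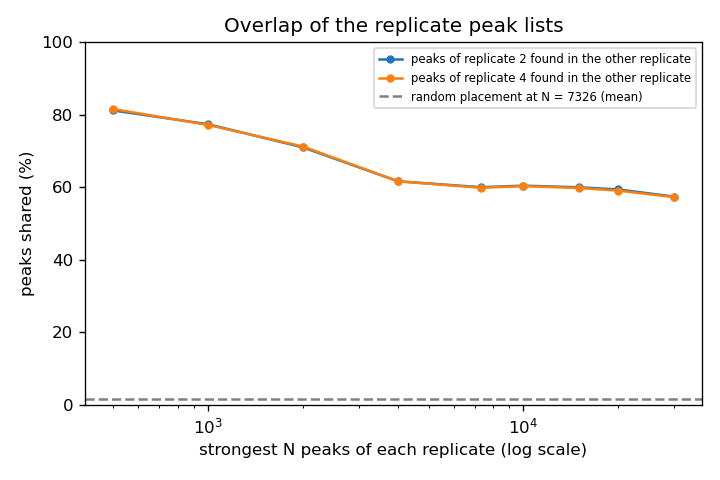
Percentage of peaks shared between the replicates (y axis) for the strongest N peaks of each (x axis, log scale), with points for each direction and a dashed line for random placement. The shared percentage was 81.2% to 81.6% for the strongest 500 peaks and 57.3% to 57.4% for all 30000.

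Most of the remaining strong peaks lay at promoters and introns. Trl, which encodes the GAGA factor, held the peak ranked 5 in an intron 1542 bp downstream of a start (chromosome 3L, 14759248 to 14759777, signal values 1981 and 1557 in replicates 2 and 4). An intronic peak in ush, a GATA cofactor gene, had cbt, a zinc-finger transcription factor gene, as the gene of its nearest start (chromosome 2L, 480577 to 481356). Cat, which encodes catalase, had a peak 316 bp downstream of a start (chromosome 3L, 18822584 to 18823228), and CenG1A had a peak 100 bp upstream of a start (chromosome 2L, 13835289 to 13835675). The peaks nearest to CG14100, Svil, CG18549 and larp were also promoter peaks, those of CG11050 and CG32772 were intronic, that of CG31668 was intergenic, and that of the non-coding gene lncRNA:CR44619 lay in an exon of lncRNA:Vinr. Of the 15 strongest peaks, 8 were promoter peaks and 5 were intronic. All 15 ranked 18 or better in both replicates.

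The tagged gene itself carried no strong peak. No IDR-thresholded peak lay within 20 kb of CG6276 (chromosome 3R, 15318203 to 15320069, minus strand). The pooled list had 2 peaks there, ranked 23431 and 26161 with signal values of 44.2 and 39.1, where the density of the chromosome would give 9.29. Replicate 2 had 4 weak peaks in this region and replicate 4 had 0. These lists of fixed length do not show whether the tag is present.

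Promoters held 2373 of the 7326 IDR-thresholded summits, or 32.4% (95% interval 31.3% to 33.5%). The other peaks of the pooled list had 15.1% of summits at promoters (odds ratio 2.69, two-sided Fisher exact test, p = 1.47e-208), and random placement gave 13.5% on average. The share was 35.5% in replicate 2 and 31.4% in replicate 4. Introns held 3628 summits (49.5%), against 54.7% of the other peaks and 39.4% by random placement, and intergenic sequence held 1118 (15.3%), against 25.5% and 27.4%. Coding exons held 14 summits (0.191%, 95% interval 0.114% to 0.321%), against 1.62% of the other peaks and 13.8% by random placement. The 5′ UTR, 3′ UTR and other exon classes each held under 1% of summits, with 69, 53 and 71.

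The strongest peaks were at promoters more often than the rest. Among the 1466 peaks with the highest signal values 42.7% of summits were promoter summits (95% interval 40.2% to 45.2%), against 29.8% of the 1465 with the lowest (odds ratio 1.75, two-sided Fisher exact test, p = 4.61e-13). The groups of equal size between them had 29.7%, 29.8% and 439 of 1465. Promoter summits sat a median of -107 bp from the start (interquartile range -244 to 81), and 66.5% were upstream (exact two-sided binomial test against 50%, p = 7.49e-59). The median was -100 bp in replicate 2, -113 bp in replicate 4 and -42 bp for the other peaks of the pooled list.

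**Figure D2:**
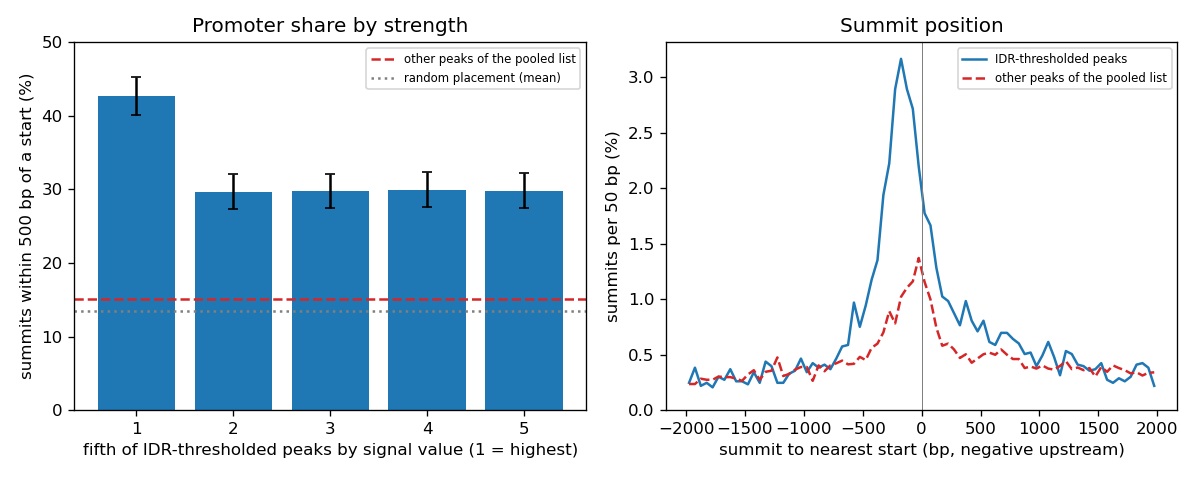
Left, percentage of summits within 500 bp of a transcript start (y axis) in 5 groups of IDR-thresholded peaks of equal size ordered by signal value (x axis), with bars for the percentage, 95% Wilson intervals, and lines for the other pooled peaks (15.1%) and random placement (13.5%). Right, percentage of summits per 50 bp (y axis) by distance to the nearest start (x axis, negative upstream), where the IDR-thresholded peaks are densest upstream of the start.

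Genes of the ecdysone response, the steroid hormone programme that drives metamorphosis, carried promoter peaks more often than other protein-coding genes. Of 31 listed ecdysone-response genes 17 had a promoter peak (54.8%), against 13.1% of other protein-coding genes (odds ratio 8.04, two-sided Fisher exact test, adjusted p = 6.69e-07). The strongest were at Ldh, an ecdysone-inducible gene for lactate dehydrogenase (signal value 1188), at the nuclear receptor gene Eip75B (1124) and at Eip93F, a late-acting transcription factor gene (833.6). The receptor genes EcR and usp, picked after their values were seen, also had promoter peaks, with signal values of 310.7 and 270.7. The share was 45.2% in replicate 2 and 54.8% in replicate 4. The call was lost in a logistic model with the number of starts and gene length, chosen after the data were seen (odds ratio 2.63, 95% interval 1.15 to 6.01 before adjustment). It was also lost among genes with any pooled peak at a start (odds ratio 3.67, Fisher exact test, adjusted p = 0.134, the highest of its alternatives, which reached down to 7.52e-08, with an adjusted Wald p = 0.0958 in the logistic model).

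The Notch pathway, which controls cell fate choices between neighbouring cells, was the other list with over 50% of members bound; the lists were not tested against each other. Promoter peaks were found at 13 of 25 members (52.0%, odds ratio 7.16, adjusted p = 2.37e-05 by Fisher exact test), and the 13 genes had 13 separate peaks. They included the Notch target E(spl)m3-HLH (signal value 1060), the co-repressor gene gro (985.0) and neur, which encodes a ubiquitin ligase acting on Notch ligands (824.4). Of the 7 clustered E(spl) genes on the list 4 were bound. Their peaks and that of gro lay close together on chromosome 3R, between 25997148 and 26042665. Separate peaks at such neighbouring genes are not independent units of the test. The share was 52.0% in replicate 2 and 48.0% in replicate 4. The call was lost among genes with any pooled peak at a start (odds ratio 2.80, Fisher exact test, adjusted p = 0.343, with a range over its alternatives from 7.59e-06 to 0.343).

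Cytosolic ribosomal protein genes, fat body genes and chromatin regulators were bound above background by smaller margins in the main comparison. Cytosolic ribosomal protein genes had promoter peaks at 21 of 85 members (odds ratio 2.17, adjusted p = 0.0142 by Fisher exact test), led by RpL31, RpL24 and RpS15 with signal values of 401.1, 285.4 and 266.2. The peaks of RpL31 and RpL24 were matched in neither replicate list at 50% of both lengths. Their share was 30.6% in replicate 2 and 18.8% in replicate 4, and with replicate 4 alone the odds ratio was 1.57 (Fisher exact test, adjusted p = 0.176, with a range over alternatives from 0.000157 to 0.624). It was 0.416 in the stronger 50% of the IDR-thresholded peaks and 1.39 among genes with any pooled peak at a start, and neither passed the threshold. Larval serum and fat body genes had 7 of 20 (odds ratio 3.55, Fisher exact test, adjusted p = 0.0336), among them the lipid droplet gene Lsd-1, the lipid transfer particle gene Apoltp and the fatty acid synthase gene FASN1. The larval serum protein genes on the list (Lsp1alpha, Lsp1beta, Lsp1gamma and Lsp2), looked up after the data were seen, were not among the 7. Polycomb and trithorax group genes, which keep developmental genes off or on, had 9 of 30 (odds ratio 2.82, Fisher exact test, adjusted p = 0.0347), led by ph-p (signal value 1944), brm (994.2) and Trl (688.8). The ph-p peak was matched in neither replicate list at 50% of both lengths, a rule that such a wide peak can fail. The fat body call was kept in 1 of 8 alternatives, replicate 2 alone, and was lost with replicate 4 alone (odds ratio 2.89, Fisher exact test, adjusted p = 0.0829, range over alternatives 0.0194 to 0.343). The Polycomb and trithorax call was kept in 3 of 8 and lost in the stronger 50% of peaks (odds ratio 1.76, Fisher exact test, adjusted p = 0.475, range 0.00361 to 0.501).

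Chemosensory, cuticle and histone genes had promoter peaks below the background share. Odorant, gustatory and ionotropic receptors and odorant-binding proteins had promoter peaks at 6 of 230 members (2.61%, odds ratio 0.173, adjusted p = 6.69e-07 by Fisher exact test). The 3 strongest were the odorant-binding protein genes Obp83g, Obp83cd and Obp99b, and the receptor genes Gr10a and Gr10b had none. For the chemosensory list the share was 1.30% in replicate 2 and 2.61% in replicate 4. Cuticle proteins had 2 of 121, at Cpr50Ca and Cpr49Ah (odds ratio 0.109, Fisher exact test, adjusted p = 5.12e-05), with none at Ccp84Aa or Ccp84Ab. For cuticle proteins the share was 3.31% in replicate 2 and 1.65% in replicate 4. Replication-dependent histone genes had 0 of 111, His1:CG31617 and His1:CG33801 among them (Fisher exact test, adjusted p = 2.69e-06). No histone gene on the list had a pooled peak at a start either. Reads from near-identical gene copies, which the histone, small nucleolar RNA and transfer RNA lists can hold, may not be placed uniquely. How such reads were handled is not given in the sources used here. For the histone genes an absence of peaks therefore cannot be told from an absence of placed reads, and near-identical copies are not separate units of the test. The chemosensory call was lost among genes with any pooled peak at a start (odds ratio 0.394, Fisher exact test, adjusted p = 0.343, range over alternatives 7.45e-12 to 0.343). The cuticle call was lost in the logistic model (odds ratio 0.235, 95% interval 0.0575 to 0.961 before adjustment, adjusted Wald p = 0.125, range over alternatives, the others by Fisher exact test, 9.38e-05 to 0.125).

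Respiratory chain, proteasome and small nucleolar RNA genes were also below background. The mitochondrial respiratory chain had 3 of 87 (odds ratio 0.233, adjusted p = 0.0142 by Fisher exact test), at ND-ASHI, COX7AL2 and ND-MLRQ (the last matched in neither replicate list), with none at ATPsynB or ATPsynC. Proteasome subunits had 0 of 38, with Prosalpha1 and Prosalpha1R unbound (Fisher exact test, adjusted p = 0.0241). Small nucleolar RNA genes had 9 of 269 (odds ratio 0.245, Fisher exact test, adjusted p = 3.37e-06), at snoRNA:CG43051-a, snoRNA:Or-aca2 and snoRNA:Me28S-A2113 among others, while scaRNA:MeU1:95C-A24 and scaRNA:MeU1b-A234 had none. The peaks of snoRNA:Or-aca2 and snoRNA:Me28S-A2113 were also promoter peaks of RpS6 and RpL30. Other bound members shared peaks too, such as snoRNA:Psi28S-1232 with RpL17. Such peaks cannot be assigned to the small nucleolar RNA genes alone. For small nucleolar RNA genes the share was 4.09% in replicate 2 and 1.12% in replicate 4. The small nucleolar RNA and respiratory chain calls were lost in the logistic model, with odds ratios of 0.891 (95% interval 0.453 to 1.75) and 0.321 (0.0990 to 1.04), and among genes with any pooled peak at a start, with 0.684 and 1.29. The proteasome call was kept in 2 of 7 alternatives and lost with replicate 4 alone (odds ratio 0.182, Fisher exact test, adjusted p = 0.116, range 0.00620 to 0.460).

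The other 19 lists did not pass the threshold with these settings, although single members had some of the strongest promoter peaks. The heat shock genes Hsp27 and Hsp26 had signal values of 2869 and 551.2 (4 of 19 members bound), and the chromosomal protein gene Chro and psq had 2668 and 1562 (insulator and architectural proteins, 6 of 24). Among mitochondrial ribosomal proteins mRpS23, whose peak is also that of CenG1A, and mRpS10 had 3096 and 2226 (8 of 73), and among translation factors eIF6 and eIF4EHP had 2000.9 and 1617 (7 of 51). The kinase gene sgg and REPTOR had 1725 and 1464 (insulin and TOR signalling, 6 of 23), and the neuronal RNA-binding protein genes elav and Rbp9 had 1619 and 404.6 (neuronal genes, 5 of 38). Muscle genes had 9 of 39 bound, among them Argk1 and Msp300, and patterning genes 12 of 56, among them ct and so. Glial genes had 3 of 12 (loco, moody), humoral immunity genes 7 of 44 (cact, imd), hemocyte genes 2 of 14 (ush, srp) and midgut digestive enzymes 1 of 46 (Mal-A5). Cell death genes had 2 of 19 (hid, Diap1), autophagy genes 3 of 20 (Atg13, Atg8a), replication and cell cycle genes 4 of 41 (Dp, fzr) and aminoacyl-tRNA synthetases 2 of 33 (AspRS, HisRS). Salivary gland glue and late puff genes had 0 of 22 and small nuclear RNA genes 0 of 32. Transfer RNA genes had 48 of 290 from 30 separate peaks (odds ratio 1.43, Fisher exact test, adjusted p = 0.0639), with tRNA:Tyr-GTA-1-8 and tRNA:Ala-AGC-2-2 the strongest. The transfer RNA list passed it, above background, with replicate 2 alone (odds ratio 1.68) and within 1000 bp (1.61). Its odds ratio was 7.09 (95% interval 5.05 to 9.97) in the logistic model, above background past the threshold, and 0.449 among genes with any pooled peak at a start, below it past the threshold. Neuronal genes were below background past the threshold in the logistic model (odds ratio 0.216, 95% interval 0.0791 to 0.590). By Fisher exact test, patterning genes were above it past the threshold with replicate 4 alone (odds ratio 2.26) and insulin and TOR signalling within 1000 bp (3.18). Midgut digestive enzymes were below it with replicate 2 alone (0.121) and within 1000 bp (0.109), and small nuclear RNA genes with replicate 2 alone.

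**Figure D3:**
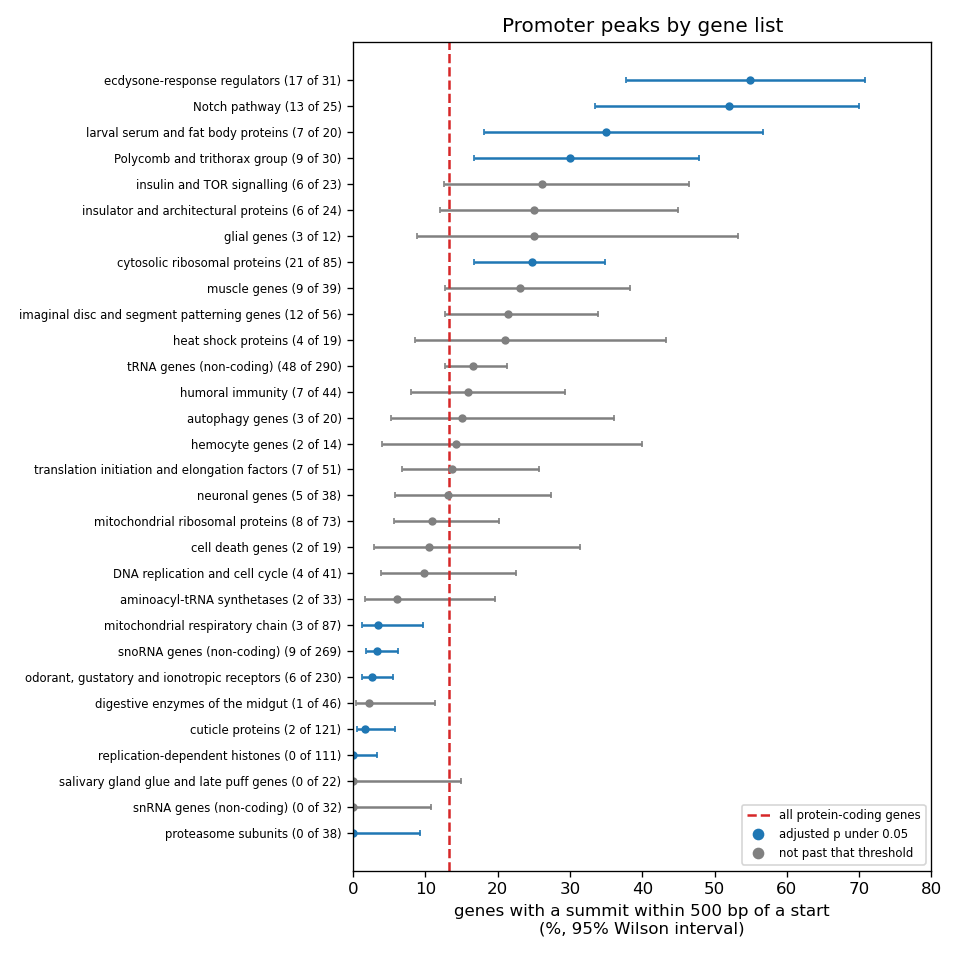
Percentage of genes with an IDR-thresholded summit within 500 bp of a start (x axis) for each of the 30 lists (y axis, with bound and total members), as points with 95% Wilson intervals and a dashed line for all protein-coding genes (13.2%). Blue points are lists with an adjusted p under 0.05, of which 5 lie above the line and 6 below it.

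The X chromosome held more peaks per length than the autosome arms. X had 62.2 IDR-thresholded peaks per Mb, against 54.3 on 2L, 50.1 on 2R, 58.9 on 3L and 51.6 on 3R. The ratio of X to the autosome arms was 1.16 for these peaks and 0.934 for the other pooled peaks (odds ratio 1.24, two-sided Fisher exact test, p = 6.74e-10), and it was 1.19 in replicate 2 and 1.12 in replicate 4. Chromosome 4 had 8 peaks (5.93 per Mb). The sample mixed males and females in a proportion not given in the sources used here.

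Sequence at the summits was rich in A and T. The TATA box consensus was found in 7.77% of summit windows and 4.60% of windows 500 bp away (exact sign test, adjusted p = 5.71e-14), and tracts of 10 A in 10.1% and 6.62% (adjusted p = 1.56e-13). The forkhead site was at 11.6% and 9.69% (exact sign test, adjusted p = 0.000858) and the GAGA element at 6.89% and 5.20% (adjusted p = 0.000103). The homeodomain core was in 1063 summit windows and 954 of those 500 bp away (exact sign test, adjusted p = 0.0286). Sites found less often at summits included the E-box CAGCTG (7.47% and 9.62%, exact sign test, adjusted p = 2.61e-05), the nuclear receptor half-site (1.24% and 1.91%, exact sign test, adjusted p = 0.00591) and the Tramtrack site (0.437% and 0.764%, adjusted p = 0.0338). The Tramtrack call was lost with replicate 4 alone (ratio 0.708, exact sign test, adjusted p = 0.271, range over its alternatives 5.89e-09 to 0.501), with the stronger 50% of peaks, with 50 bp to each side, at distal summits and against the other pooled summits. The nuclear receptor half-site call was lost against the other pooled summits (ratio 0.903, Fisher exact test, adjusted p = 0.552, range 9.69e-06 to 0.552), with the stronger 50% of peaks and with 50 bp to each side. The E-box was higher at summits, past the threshold, with 200 bp to each side (ratio 1.15) and against windows of the same GC count (1.23). Of 27 consensus sequences 5 were higher and 8 lower, and in each of those comparisons 7 were higher and 3 lower. The GAGA element, with a ratio of 1.33 over all summits, did not pass the threshold in the stronger 50% of peaks (1.05), with 50 bp to each side (1.09) or at summits over 500 bp from a start (0.895, exact sign test, adjusted p = 0.340, range over its alternatives 1.69e-91 to 0.734). Its ratio was 2.03 with windows of 200 bp to each side and 3.92 against windows of the same GC count, an alternative added after the data were seen. The homeodomain call was lost with replicate 4 alone (ratio 1.09, exact sign test, adjusted p = 0.0935, range 8.33e-06 to 0.0935). This core was lower at summits, past the threshold, with 200 bp to each side (ratio 0.896) and against windows of the same GC count (0.859). In the latter comparison the TATA box and forkhead site no longer passed the threshold (ratios 1.07 and 1.06).

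Bound promoters differed from unbound ones in the consensus sequences they held. Matches were counted on either strand anywhere in the promoter sequence, not at fixed positions. The GAGA element was in 7.23% of 1479 bound promoters and 2.81% of 12466 unbound ones (odds ratio 2.70, two-sided Fisher exact test, adjusted p = 2.84e-14). A sequence like the downstream promoter element was in 6.49% and 3.63% (odds ratio 1.85, Fisher exact test, adjusted p = 3.98e-06). The TATA box was less frequent in bound promoters, at 74 of 1479 against 9.85% of unbound ones (odds ratio 0.482, Fisher exact test, adjusted p = 1.35e-09), as was the homeodomain core, at 3.65% and 7.34% (odds ratio 0.478, adjusted p = 1.40e-07). The initiator consensus was in 29.2% and 25.2% (odds ratio 1.23, Fisher exact test, adjusted p = 0.00421), a call kept in 2 of 6 alternatives, replicate 4 alone and all distinct starts. It was lost with replicate 2 alone (odds ratio 1.02, Fisher exact test, adjusted p = 0.821, range over alternatives 4.38e-05 to 0.821), in the stronger 50% of peaks (1.06), within 250 bp (1.19) and within 1000 bp (1.12). The E-box CAGCTG, less frequent at summits than 500 bp away, was in 15.7% of bound promoters and 11.6% of unbound ones (odds ratio 1.41, Fisher exact test, adjusted p = 7.10e-05). In all, 7 consensus sequences were higher and 8 lower in bound promoters.

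Among all 7-mers, A-rich sequences led those more frequent at summits. AAAAATA was in 29.8% of summit windows and 17.6% of windows 500 bp away (ratio 1.69, exact sign test, adjusted p = 1.10e-64), followed by AAAAAAT (ratio 1.71), AAAAAAA (1.63), AGAAAAA (1.89) and TAAAAAA (1.73). Of 8192 7-mers 1122 were higher and 2284 lower at summits, against 878 and 1283 in the comparison with windows of the same GC count. The leading lower ones shared the bases GGCC: TGGCCAA (ratio 0.528, exact sign test, adjusted p = 2.04e-17), CTTGGCC (0.441), ATGGCCA (0.486), CCTGGCC (0.330) and CTGGCCA (0.487). The 10 named 7-mers kept these directions in both replicates and passed the threshold in all 8 alternatives run for each. Median GC content was 35.8% in summit windows, 42.3% in windows 500 bp away and 41.3% at the other pooled summits.

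A second family of 7-mers held CAGTG or its reverse complement CACTG. These 7-mers were picked after their values were seen. CAGTGTA was in 6.69% of summit windows and 1.73% of windows 500 bp away (ratio 3.86, exact sign test, adjusted p = 6.32e-51), and CAGTGCA in 9.36% and 3.44% (ratio 2.72, adjusted p = 4.44e-46). Their ratios were 3.94 and 2.63 in replicate 2, and 3.89 and 3.03 in replicate 4. Of the 48 7-mers that hold the core 27 were higher and 1 lower. Matches were not densest at the summit. CAGTGTA had 13.8 matches per 1000 summits in each 25 bp step from 75 to 100 bp to either side, against 5.05 from 0 to 25 bp and 3.41 from 200 to 225 bp. CAGTGCA had 20.6, 6.76 and 5.46 at those distances, while AAAAAAA had 115.1, 183.9 and 87.4.

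**Figure D4:**
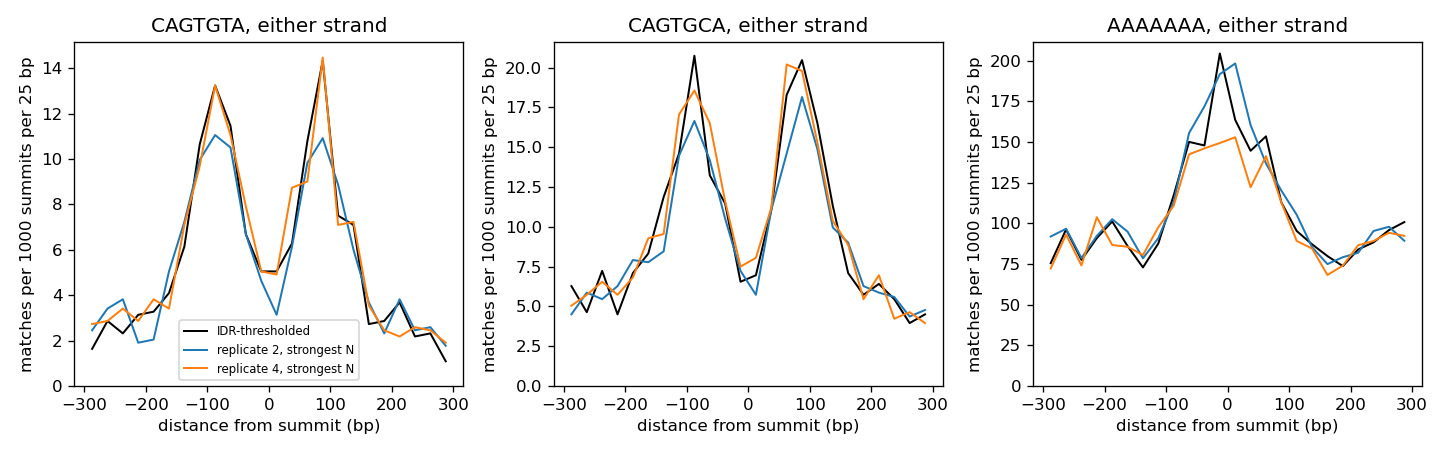
Matches per 1000 summits in 25 bp steps (y axis) by distance from the summit in bp (x axis) for CAGTGTA, CAGTGCA and AAAAAAA on either strand, with lines for the IDR-thresholded peaks and the strongest 7326 peaks of each replicate. The CAGTG sequences have a maximum on each side of the summit, and AAAAAAA is densest near it.

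The lists on the older genome build dm3 were close in size to those on dm6. The IDR-thresholded list had 7341 peaks on dm3 and 7326 on dm6, with median signal values of 240.2 and 251.5. Of the 7326 signal values on dm6, 0 were found unaltered at the printed precision on dm3. Positions were not compared between the builds.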

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

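Promoter share, its difference by strength, summit offset and X density kept their direction and side of the threshold with the stronger peaks, single replicates and, where run, other promoter windows or comparison sets. Depth is unknown. Alternatives with equal GC counts, merged regions, other pooled summits for 7-mers and the logistic model were chosen after seeing the data. The cause of the changes below was not tested.

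Replicate overlap moved from 59.9% to 73.7% with at least 1 bp, 42.0% with 80% of both lengths, 65.8% with summits within 100 bp, 77.3% for N = 1000 and 62.7% for N of 50%. Spearman rho moved from 0.686 to 0.640 with 1 bp and 0.666 with summits. The intron and intergenic share, 64.8%, was 61.6% to 65.7% in single replicates, and 73.9% and 54.8% with promoter windows of 250 and 1000 bp.

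Lists above background numbered 5, then 2 with the stronger peaks, 3 by nearest start, 3 in the logistic model and 0 among genes with any pooled peak at a start (1 at an unadjusted p under 0.05, Fisher exact test). Lists below numbered 6, then 2 in that background and 2 in the logistic model, of which 1 in each was among the 6. The logistic model could not be fitted to 2 of the 6, which had 0 bound members, and 1 of the 6 had no member in that background. Motifs lower at summits numbered 8, then 4 with 50 bp, 3 with 200 bp, 4 against other pooled summits and 3 at equal GC. Lower 7-mers fell from 2284 to 1283 at equal GC. Promoter motifs higher numbered 7, then 4 with the stronger peaks; lower ones 8, then 5 with the stronger peaks, 5 in each single replicate and 4 within 250 bp.

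Odds ratios that changed side of 1 follow. With the stronger peaks: cytosolic ribosomal 0.416, mitochondrial ribosomal 1.21, tRNA 0.888, cell death 1.34, immunity 0.834, hemocyte 0.877. Among genes with any pooled peak: mitochondrial ribosomal 3.45, respiratory chain 1.29, tRNA 0.449, muscle 0.642, patterning 0.465, cell cycle 1.15, hemocyte 0.343. In the logistic model: mitochondrial ribosomal 2.13, muscle 0.424, patterning 0.557, hemocyte 0.456. By nearest start: translation factors 0.483, tRNA 0.893, neuronal 1.17. Within 1000 bp: autophagy 0.870, cell cycle 1.01, hemocyte 0.821. In single replicates: neuronal 1.23 to 1.80, cell death 0.793 to 1.02, hemocyte 0.911 to 1.12, and E-box CACGTG in promoters 0.667 to 1.05.

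Motif ratios that changed side of 1 were GAGA at distal summits, 0.895. With 200 bp they were E-box motif 5, 1.15, Adf1, 1.12, homeodomain, 0.896, CA repeat, 1.51, and MADF, 1.099. At equal GC they were E-box motif 5, 1.23, AP-1, 1.04, Adf1, 1.39, homeodomain, 0.859, CA repeat, 2.03, and MADF, 1.45.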

Other observations

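The patterns weighed in this part were noticed in the same data. The bounds for each test were set before its result was seen. The background of genes with any pooled peak at a start and the summits over 500 bp from a start were chosen before the data were examined, while the comparison windows of equal GC count, the comparison with other pooled summits for 7-mers, the logistic model, the class of all A/T-only 7-mers, the windows of equal GC count for the extended core, the positions of CAGTG and the direction in which its flanking matches read were chosen after the data had been examined. No biological explanation was tested against another group, since the design has a single group. The tests of the core within 50 bp of the summit were fixed before it was seen that the core is densest 75 to 100 bp away, and they were kept.

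The CAGTG sequences were also more frequent than 500 bp away when summits at annotated promoters were left out. At summits over 500 bp from a start CAGTGTA had a ratio of 4.92 to windows 500 bp away and CAGTGCA 3.40, and 28 of the 48 7-mers with the core were higher there. The GC content of the sequence rose from 34.8% within 25 bp of the summit to 40.1% at 75 to 100 bp and 44.2% at 200 to 225 bp. Within 50 bp of the summit the core was found at 13.2% of the 1466 summits with the highest signal values (95% interval 11.6% to 15.1%) and 20.8% of the 1465 with the lowest (18.8% to 22.9%). The windows 500 bp away from those summits had 17.1% and 13.9%. Over all summits the core was at 17.7%, against 16.0% in windows 500 bp away and 19.7% at the other pooled summits.

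For the CAGTG family, the GC count of the whole window alone was argued against. The median ratio of its 48 7-mers to windows of equal GC count was 1.48 (95% bootstrap interval 1.44 to 1.65), above the bound set. That comparison does not set the family apart. The MADF sequence, lower at summits than 500 bp away, was in 2.89% of summit windows and 2.00% of equal-GC windows. The Adf1 site, lower too, had 0.792% and 0.569%, while others, such as the nuclear receptor half-site, stayed lower. GC content also changed within the window, so base composition more broadly stays open. Exact copies of a repeated sequence were argued against too. The share of matches within 50 bp of a summit whose 31-base surroundings occurred once was 1 (1455 matches). All 4140 matches within 100 bp also had surroundings that occurred once. Copies that have diverged would count as occurring once as well, so they were not tested. A property of any pooled region stays open, with a median ratio to the other pooled summits of 1.13 (1.07 to 1.198): by Fisher exact test 21 of the 48 were higher than there (CAGTGTA with a ratio of 1.89 and CAGTGCA with 1.56) and 4 were lower. A sequence preference of CG6276 or a partner may contribute. An extended core was tested, its surroundings learnt on chromosome 2 and CAGTG itself picked on all chromosomes. It was 2.25 times (1.86 to 2.78) as frequent at summits of the other chromosomes as 500 bp away. The ratio to windows of equal GC count was 2.18 (1.90 to 2.51), which argues against the GC count of the whole window alone for it. However, it was in 4.81% of the strongest of those summits and 6.90% of the weakest (two-sided Fisher exact test, p = 0.0520). The further condition set for it, a higher share in the strongest, was thus not met. Transcription initiators pointing away from the summit are another candidate explanation, and 57.8% (56.0% to 59.6%) of 2900 core matches in a stretch of flank that begins 50 bp from distal summits read away from the summit, against 53.1% nearer the summit and 52.7% in a stretch that begins at 200 bp. That lies between the bounds set for it, and over all summits the value was 54.5% in replicate 2 and 57.2% in replicate 4, so this stays open. The initiator consensus TCAGTY was in 18.6% of summit windows and 18.3% of windows 500 bp away (exact sign test, adjusted p = 0.752). Its last base is C or T, so a match to it does not hold CAGTG and cannot decide the question.

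All 64 7-mers made of A and T alone were more frequent at summits than 500 bp away, with a median ratio of 1.53. Their median ratio to the other pooled summits was 1.37 (95% bootstrap interval 1.35 to 1.42), above the bound set against a property of any pooled region. The ratio was 1.43 (1.37 to 1.47) for the 5 of them with the smallest p. The other pooled summits had a higher median GC content, 41.3% against 35.8%, and can include background. These ratios thus cannot tell such a property from base composition, and this stays open. Base composition is a candidate explanation for the class that met the bound set for it, with a median ratio to windows of equal GC count of 1.04 (1.01 to 1.06). For those 5, which were picked for the pattern and leave out AGAAAAA, that ratio was 1.26 (1.22 to 1.31), so whether composition accounts for them stays open.

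For the ecdysone-response and Notch lists, neither technical explanation could be excluded for both lists. With the number of starts and gene length as covariates the smaller odds ratio was 2.63 (95% interval 1.15 to 6.01), for the ecdysone list, and that of the Notch list was 6.80 (2.79 to 16.6). Among genes with any pooled peak at a start, the smaller was 2.80 (0.912 to 8.62), for the Notch list, and that of the ecdysone list was 3.67 (1.23 to 10.9). That background comes from the same immunoprecipitation and 1842 of its 3424 genes are those with an IDR-thresholded promoter peak, so it does not measure accessibility, which stays open, and the intervals are wide because the lists are short.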
